A study of Mus musculus with 6 samples.

How the data were processed

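The series holds RNA-seq of region I of the mouse epididymis in 6 libraries, 3 from Pten knockout and 3 from control samples. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit, and mRNA libraries made with Illumina TruSeq reagents were sequenced on an Illumina instrument. The deposited table holds whole-number read counts per gene, not normalized, for 41128 Ensembl gene identifiers. Per the submitters' processing notes, STAR 2.4.0, featureCounts 1.4.4, DESeq2 1.4.5 and the genome build GRCm38 were used, with no role or order given there. The annotation release, the treatment of reads that match several genes and whether counting used the strand are not given in the sources used here. Reads of near-identical genes and of genes that overlap on opposite strands can therefore have been lost or assigned to either. Among the genes that met the naming rule given below, not all of which the report names, exon overlaps with another annotated gene were found for 28. Not all are repeated beside the values. Opposite-strand overlaps also hold for Tjp3, Plin4, Eng, Tpi1, Me1, Dst, Krt10, Odf2 and Hspa1a. Same-strand overlaps also hold for Slc9a1, Pdgfra and Rpl18a.

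Columns were assigned to samples by the name in the description label. The table has 2 further columns whose names match no sample of the series, and these were used in no step. No row was without a gene identifier (0 of 41128). Gene symbols and coordinates come from GENCODE M21 on GRCm38. Of the identifiers, 40254 matched it without the version suffix, 20591 with the same version, and 874 had no match and kept their identifier.

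Library totals were 14165011, 17467885 and 15591656 counts in controls 335, 337 and 344 and 19120471, 14735363 and 17532961 in knockouts 333, 336 and 345. At this depth 3 counts correspond to between 0.157 and 0.212 CPM, so transcripts below that level could be missed, and this covers counting error only. Pairs of libraries of a group had a Pearson correlation of log CPM across genes of 0.978 to 0.990, where genes are not independent replicates. The chi-square of their counts per degree of freedom was 6.53 or more, over genes with 20 or more counts in the pair, so no pair agreed within sampling noise and each library was counted as 1 sample.

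The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest, two-sided) on the deposited counts, with TMM factors and the filterByExpr filter, which left 14450 genes. The fit had a single term for the group. P values were adjusted by the Benjamini-Hochberg method and called below 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values use the TMM-scaled library sizes. TMM factors lay between 0.975 and 1.04.

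There were 44 gene lists, fixed before the data were examined, for signalling pathways, segments and cell types of the epididymis, transporters and channels, secreted protein families, metabolism and stress. Lists of gene families were taken by a pattern of the gene name over protein-coding genes. The symbols Rhbg, Hbb-b1 and Hbb-b2 were not found in the table. Lists with 5 or more tested members, 41 in all, were tested with camera of limma 3.58.1 on the edgeR data with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. An estimated correlation and fry were alternatives. For each list the members called over all genes are given beside those adjusted over the list alone.

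Genes named in the text were chosen by a rule fixed before the data were examined. It takes Pten, then the 10 largest rises and 10 largest falls among called genes with a mean of 5 CPM or more in the higher group and no overlap between groups, leaving out predicted genes and pseudogenes. It takes up to 4 called members of each list with the smallest adjusted p, or up to 2 with the smallest p if none was called, and up to 5 solute carriers, aquaporins or ABC transporters each way under the same conditions. Genes named outside this rule are said to have been picked after their values were seen.

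Alternatives fixed before the data were examined were RLE factors, DESeq2 1.42.0, limma-voom, limma-voom with sample quality weights, no filter except for genes at 0, a mean CPM of 1 or more, removal of the 20 most abundant genes, and leaving out each library. A term for the range of the sample number in the titles, whose meaning the labels do not give, an adjusted p below 0.01 and a log2 fold change of at least 1 were further ones. For DESeq2 the lists were tested with camera on its Wald statistics. Added after seeing the data were a fit without control 337, which had the lowest Rnase10 level of the controls, and knockout 336, which lay furthest from the controls on the first principal component, and a fit with smooth trends over GC content and transcript length removed from each library. The sample numbers are not shared between groups, so there was no paired fit.

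The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of these libraries over 14450 genes, with 200 genes changed. It recovered 38 of 67 genes changed 1.5-fold, 58 of 67 changed 2-fold and 63 of 66 changed 4-fold. Of 171 calls 12 were false, or 7.02%. Recovery depends on the share of changed genes, and 3238 genes were called in the data, so these rates need not hold there. With no change simulated the procedure called 0 genes and 0 lists, and with 1 list raised 1.5-fold it called that list alone. Simulated genes varied independently of each other, whereas the estimated correlation was 0.665 in the cell cycle list and 0.627 in the ribosomal protein list. The simulation therefore cannot show the error rate of camera in lists of correlated genes.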

Results

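RNA from region I of the mouse epididymis was sequenced in 6 libraries, 3 from Pten knockout samples and 3 from control samples. The knockout was made by crossing floxed Pten mice with a line that expresses Cre recombinase from the Rnase10 promoter, which is active in the principal cells of the initial segment, the part of the epididymal duct that first receives sperm from the testis. Pten is a phosphatase that opposes PI3-kinase signalling. Total counts per library ranged from 14165011 to 19120471, and between 18900 and 19871 genes had at least 1 count in a library. Libraries are named by their group and the sample number in the labels, with controls 335, 337 and 344 and knockouts 333, 336 and 345. The labels do not say that these samples came from separate animals, so p-values measure the spread between these samples, which could in part be technical. The secreted glutathione peroxidase gene Gpx5 held the largest share of counts in each library, between 3.37% and 5.55%. On the 1000 most variable genes, the first principal component held 74.4% of the variance and separated the groups, with controls between -33.4 and -26.4 and knockouts between 19.7 and 39.6. Knockout libraries differed more among themselves than controls did, with a chi-square per degree of freedom between pairs of 12.5 to 33.2 against 6.53 to 10.8.

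Pten transcripts were lower in the knockout, at 61.3 ± 5.03 CPM (counts scaled by library size; SD, n = 3) against 97.2 ± 19.9 CPM in controls. Control 335 had 110.6, control 337 74.4 and control 344 106.6 CPM, and knockouts 333, 336 and 345 had 67.1, 58.0 and 58.7 CPM, so each knockout lay below each control. The gene (ENSMUSG00000013663) lies on chromosome 19 at 32757497 to 32826160 of GRCm38. Its fall was -0.66 (SE 0.15) on the log2 scale, with a Benjamini-Hochberg adjusted p of 0.0190 in edgeR's quasi-likelihood test. A count over the whole gene also takes in transcripts that lack a deleted exon and transcripts of cells without Cre activity. The call was lost without control 335 (-0.56, adjusted p = 0.0529), control 344 (-0.59, 0.0631), knockout 336 (-0.62, 0.103) or knockout 345 (-0.63, 0.0755), and with no filter on low counts (-0.65, 0.0661), all by the same edgeR test.

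The comparison asks how the tissue's transcripts differ when Pten is removed from this epithelium. Of 21 target genes of ERK signalling 8 fell, of 26 cell cycle genes 23 rose, and of 253 solute carrier genes 57 rose and 40 fell in the knockout. The ERK and cell cycle lists passed a set test with a preset correlation, with adjusted p = 0.580 for each with an estimated correlation. The transcription factor gene Etv4 fell 5.58-fold, the insulin receptor substrate gene Irs2 4.71-fold and the growth factor gene Bmp7 10.1-fold, while the prostaglandin transporter gene Slco2a1 rose 4.66-fold and the proliferation marker Mki67 2.93-fold. Of 14450 genes tested, 3238 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1855 higher and 1383 lower in the knockout. At least a 2-fold change was seen in 614 of those higher and 284 of those lower. Among the called genes 3228 had no overlap between the 3 knockout and the 3 control CPM values. Over all genes tested, 40.7% had no overlap, where chance gives 10%. Every gene below that is said to have risen or fallen had no such overlap. Without control 344 the test called 1955 genes, 1152 higher and 803 lower, and without control 335 it called 909 lower.

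**Figure D1:**
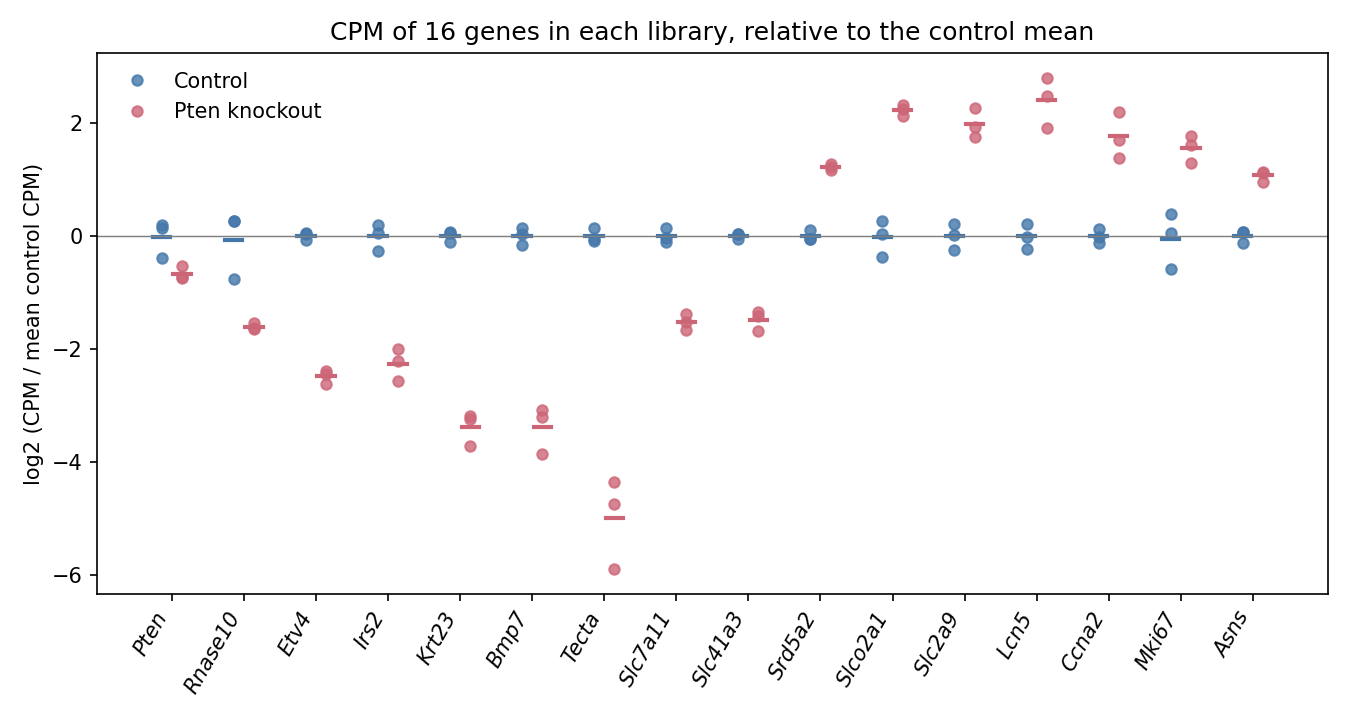
Log2 of the CPM of 16 genes in each library divided by the mean of the 3 controls, with 1 point per library and a short line at the mean of each group. The points of the 3 knockouts lie on one side of the 3 controls for each gene, with Tecta falling by 4.84 and Lcn5 rising by 2.44 in the fitted log2 fold change.

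The largest rises were found in genes that were scarce in controls. Akr1c18, which encodes a steroid dehydrogenase that inactivates progesterone, rose 85.0-fold, from 0.237 ± 0.176 to 21.9 ± 2.46 CPM (SD, n = 3), with a log2 fold change of 6.41 (SE 0.27). It lies on chromosome 13 at 4132615 to 4150654. Slco1c1, a thyroid hormone transporter on chromosome 6 at 141524368 to 141570177, rose 30.8-fold, the inflammasome sensor gene Naip1 25.9-fold and the orphan nuclear receptor gene Esrrb 28.4-fold. Patl2, which encodes an RNA-binding protein known from oocytes, rose 30.7-fold, Tmem238l 21.4-fold and Rab44 21.1-fold. Akr1c18 and Naip1 belong to families of near-identical genes among which reads can be divided uncertainly. The rises of Gpa33 (log2 fold change 6.38, SE 0.98), of the vitamin D binding protein gene Gc (5.35, SE 1.18) and of Asb11 (4.23, SE 0.91) varied most between knockouts. Gc had 25.9, 225 and 71.9 CPM in knockouts 333, 336 and 345. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the call of Gpa33 was lost without control 337 (6.35, adjusted p = 0.0583) or control 344 (5.89, 0.0595). The call of Gc was lost without control 335 (5.19, adjusted p = 0.128), 337 (5.60, 0.125) or 344 (5.30, 0.152) or knockout 345 (5.57, 0.0897). That of Asb11 was lost without control 335 (4.78, 0.0825), 337 (3.98, 0.110) or 344 (4.03, 0.125) or knockout 345 (4.31, 0.0621). Without knockout 336 the values of Gc and Asb11 were 4.22 and 3.49. Without control 335 those of Slco1c1, Patl2, Gpa33 and Tmem238l were 5.90, 5.81, 7.12 and 5.28, and without control 337 that of Akr1c18 was 7.26. With limma-voom the calls of Gpa33, Gc, Tmem238l, Rab44 and Asb11 were lost (adjusted p = 0.154, 0.207, 0.0527, 0.0822 and 0.183), and with sample weights those of Gpa33, Gc and Asb11 (0.0708, 0.0965 and 0.0742). Gc and Asb11 were also lost with no filter on low counts (0.0626 and 0.0739) and with a term for the sample number range (0.0838 and 0.0560). Without control 337 and knockout 336 together, an alternative chosen after seeing the data, Gpa33, Gc, Rab44 and Asb11 were lost (0.0762, 0.111, 0.0883 and 0.0863).

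The largest falls were found both in abundant and in scarce genes of the control tissue. Tecta, known as a component of the tectorial membrane of the inner ear, fell 28.7-fold, from 245 ± 21.2 to 8.43 ± 4.02 CPM (SD, n = 3; chromosome 9, 42329619 to 42399929). Tenm4, a teneurin gene on chromosome 7 at 96171246 to 96911093, fell 41.3-fold from 66.5 ± 11.1 to 1.64 ± 1.004 CPM. The keratin gene Krt23 fell 10.3-fold from 362 ± 23.6 CPM, Bmp7 10.1-fold from 144 ± 14.7 CPM, and Zap70, a kinase known from T-cell receptor signalling, 14.3-fold from 87.5 ± 5.15 CPM. Ffar2, a receptor for short-chain fatty acids, fell 26.0-fold, the somatostatin receptor gene Sstr1 34.3-fold, Steap1 15.6-fold, the piRNA methyltransferase gene Henmt1 14.9-fold and C1ql4 11.3-fold. Exons of Tenm4 and Henmt1 overlap genes on the opposite strand, and counting by strand is not stated, so a part of their reads could belong to those partners. Without knockout 336 the log2 fold change of Steap1 was -4.89, against -3.97 with all libraries.

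Of 21 tested genes induced by ERK signalling, 8 fell and 0 rose, and 11 fell when adjusted over the list alone. Etv4 fell by 2.48 (SE 0.08), from 148 ± 6.52 to 26.4 ± 2.13 CPM (SD, n = 3). The signalling inhibitor genes Spry1 and Spred1 fell by 0.89 (SE 0.10) and 0.53 (SE 0.08), and the ephrin receptor gene Epha4 by 0.96 (SE 0.11), all on the log2 scale. The median log2 fold change of the list was -0.41, and it stood apart from other genes in the camera set test with a preset correlation (Benjamini-Hochberg adjusted p = 1.12e-07 over 41 lists), with an adjusted p = 0.580 with an estimated correlation. In the list of PI3K-AKT pathway components, 2 of 28 rose and 7 fell (3 and 8 adjusted over the list alone). The regulatory subunit gene Pik3r3 rose by 0.87 (SE 0.08) and Mtor by 0.53 (SE 0.06), and the growth factor receptor gene Igf1r fell by 1.07 (SE 0.13). Of 23 FOXO target genes, 1 rose and 5 fell, by both adjustments, among them Irs2, which fell by 2.24 (SE 0.17), the cell cycle inhibitor gene Cdkn1b, which fell by 0.50 (SE 0.08), and the apoptosis gene Bcl2l11, which rose by 0.66 (SE 0.10). Irs2 has an exon overlap with a gene on the opposite strand. The cell cycle inhibitor gene Cdkn1a, outside this list and picked after its values were seen, rose by 2.30 (SE 0.38). Its edgeR call was lost without control 344 (2.18, adjusted p = 0.0531) or knockout 336 (2.21, 0.0561). Of 9 tested genes with symbols that begin with Cdkn, 4 were called higher and 2 lower. The PI3K-AKT list (camera adjusted p = 0.599) and the FOXO list (0.0976) did not pass with a preset correlation, and the FOXO list passed without knockout 333 (0.0432) and with no filter on low counts (0.0311).

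Of 26 cell cycle genes tested, 23 rose and 0 fell, and 24 rose when adjusted over the list alone, with a median log2 fold change of 1.28. The cyclin gene Ccna2 rose 3.44-fold, from 2.02 ± 0.172 to 7.01 ± 2.02 CPM (SD, n = 3), the kinesin gene Kif20a 3.005-fold, Mki67 2.93-fold and the ribonucleotide reductase gene Rrm2 2.76-fold. All 4 stayed at low levels, and the summed CPM of the list was 153 in controls and 250.3 in knockouts. Exons of Ccna2 and Kif20a overlap a gene on the opposite strand. Camera with a preset correlation gave the list a Benjamini-Hochberg adjusted p = 4.34e-10, and an adjusted p = 0.580 with an estimated correlation.

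Of 81 ribosomal protein genes tested, 26 fell and 0 rose, and 37 fell when adjusted over the list alone, with a median log2 fold change of -0.20. The muscle paralogue Rpl3l fell by 0.77 (SE 0.08), Rplp0 by 0.40 (SE 0.08), Rpl18a by 0.39 (SE 0.07) and Rpl38 by 0.33 (SE 0.07). Reads of ribosomal protein genes can be shared with their many processed pseudogenes. Camera with a preset correlation gave a Benjamini-Hochberg adjusted p = 2.59e-06, and an adjusted p = 0.714 with an estimated correlation. With fry the list did not pass (adjusted p = 0.0574).

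The series title names transporter activity, and solute carrier genes moved both ways. Of 253 tested, 57 rose and 40 fell, and 65 rose and 44 fell when adjusted over the list alone. Over all 14450 genes tested, 22.4% were called in either direction. That is a smaller share than among the solute carriers, of which 156 of 253 were not called. Whether the shares differ between genes of like abundance was not tested. The median log2 fold change of the list was 0.03, and camera found no net direction apart from other genes (Benjamini-Hochberg adjusted p = 0.663). Camera weighs net direction, so it cannot tell whether more solute carriers than other genes changed both ways. With fry, which does not compare with other genes, the list passed (adjusted p = 0.0350, and 0.000165 for change in either direction). The largest rises after Slco1c1 were those of Slc46a2, which rose 12.3-fold from 2.04 ± 1.04 to 24.4 ± 3.66 CPM (SD, n = 3), the fructose transporter gene Slc2a5, which rose 4.72-fold, Slco2a1, which rose 4.66-fold from 41.7 ± 8.96 to 195 ± 13.2 CPM, and Slc22a23, which rose 4.30-fold. The largest falls were those of the organic cation exporter gene Slc47a2, 4.81-fold lower, the GABA transporter gene Slc6a13, 3.79-fold lower, Slc29a4, 3.47-fold lower, the cystine transporter gene Slc7a11, 2.88-fold lower at 29.8 ± 3.01 against 85.7 ± 7.77 CPM, and Slc41a3, 2.78-fold lower. Slc45a3 fell 2.39-fold from a mean of 225 CPM in controls, and exons of Slc45a3 and Slco2a1 overlap other annotated genes. The edgeR call of Slc6a13 was lost without control 337 and knockout 336 together (-1.82, Benjamini-Hochberg adjusted p = 0.0555), an alternative chosen after seeing the data. The name pattern of this list also takes in a few scaffold proteins whose symbols begin in the same way, such as Slc9a3r1.

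Transporters were also grouped by substrate. Of 17 sugar and monocarboxylate transporters, 7 rose and 0 fell (8 and 1 adjusted over the list alone). The urate and hexose transporter gene Slc2a9 rose by 1.99 (SE 0.16), Slc2a5 by 2.24 (SE 0.26) and the monocarboxylate transporter gene Slc16a1 by 1.05 (SE 0.21) on the log2 scale. The list passed camera with a preset correlation (Benjamini-Hochberg adjusted p = 0.00263), with an adjusted p = 0.580 with an estimated correlation. Of 26 amino acid transporters, 5 rose and 5 fell (7 and 5 adjusted over the list alone). Slc7a4 rose by 1.05 (SE 0.08) and the neutral amino acid transporter gene Slc1a4 by 0.64 (SE 0.12), whereas Slc7a11 fell by 1.52 (SE 0.10) and the glutamine transporter gene Slc1a5 by 0.36 (SE 0.07). Exons of Slc7a4 overlap a gene on the opposite strand. Of 12 tested transporters of organic cations, carnitine and nucleosides, 5 rose and 1 fell (5 and 2 adjusted over the list alone), with Slc44a4 at 0.71 (SE 0.08) and Slc29a4 at -1.79 (SE 0.11). Neither list passed camera (adjusted p = 0.794 and 0.790).

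**Figure D2:**
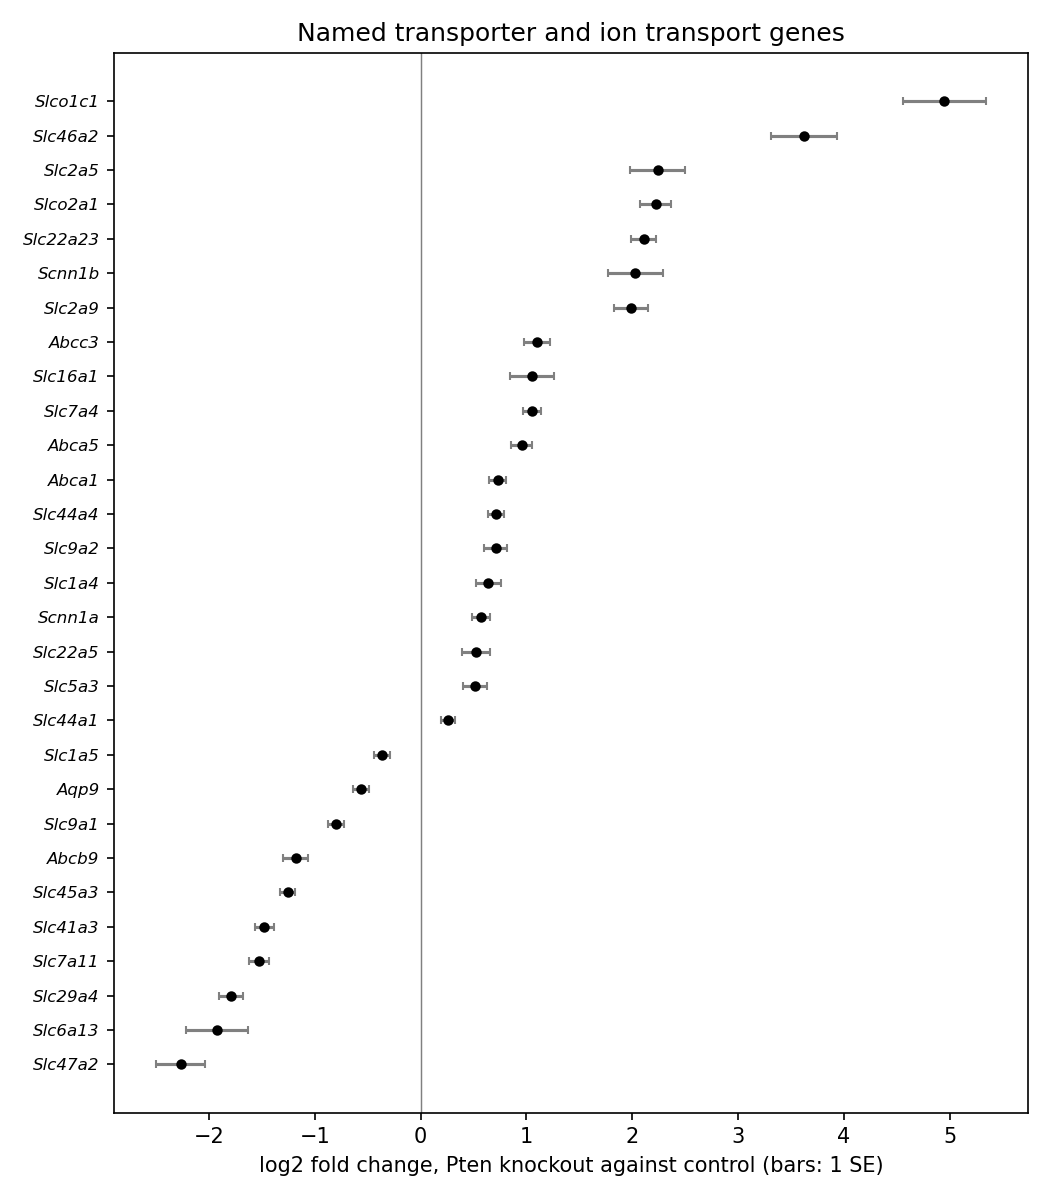
Log2 fold change, knockout against control, of 29 named transporter and ion transport genes, with bars of 1 SE on each side. Of these, 19 lie above 0 and 10 below, from -2.27 for Slc47a2 to 4.95 for Slco1c1.

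Genes of sodium, proton, chloride and bicarbonate transport, which serve the acidification and water balance of the epididymal lumen, were measured as a list. Of 27 tested, 9 rose and 3 fell by both adjustments. The epithelial sodium channel genes Scnn1b and Scnn1a rose by 2.03 (SE 0.26) and 0.57 (SE 0.09), and the sodium-proton exchanger genes Slc9a2 and Slc9a1 rose by 0.71 (SE 0.11) and fell by 0.80 (SE 0.08). The chloride channel gene Cftr, picked after its values were seen, fell by 1.10 (SE 0.19), from 144 ± 8.36 to 67.2 ± 17.6 CPM (SD, n = 3). Of 96 ion channel genes, 19 rose and 7 fell (21 and 9 adjusted over the list alone), with the potassium channel gene Kcna1 rising by 2.80 (SE 0.16), the calcium channel gene Trpv6 by 1.36 (SE 0.11) and Cacna2d3 falling by 0.85 (SE 0.10). Of 23 V-ATPase subunit genes, whose products pump protons, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with Atp6ap1 rising by 0.71 (SE 0.08) and Atp6v0d2 falling by 0.73 (SE 0.09). Of 36 ABC transporter genes, 6 rose and 3 fell by both adjustments, with the cholesterol exporter gene Abca1 rising by 0.73 (SE 0.08), Abca5 by 0.96 (SE 0.10) and Abcb9 falling by 1.18 (SE 0.12). Aqp9, a channel for water and glycerol, fell by 0.56 (SE 0.08), and it was the sole aquaporin of 4 tested to pass, also when adjusted over the list alone. None of the 4 lists that could be tested passed camera, with Benjamini-Hochberg adjusted p values of 0.299, 0.175, 0.144 and 0.284 in this order, and the aquaporins were too few for it. With limma-voom the V-ATPase list passed (0.0490, and 0.0345 with sample weights).

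Markers of the initial segment and secretory genes of the caput, the next stretch of duct, moved in both directions. Of 19 tested initial segment markers, 6 fell and 2 rose (10 and 5 adjusted over the list alone). The metalloprotease gene Adam28 fell 1.79-fold to 2581 ± 199 CPM from 4616 ± 163 CPM (SD, n = 3), the cystatin gene Cst8 1.72-fold and the receptor gene Lgr4 1.403-fold, while the defensin gene Defb42 rose 1.57-fold. Rnase10, whose promoter drives Cre here and which was picked after its values were seen, fell 3.04-fold. It had 10385, 5088 and 10377 CPM in controls 335, 337 and 344 and between 2751 and 2973 CPM in the knockouts. Its call was lost without knockout 336 (log2 fold change -1.58, edgeR adjusted p = 0.0966) and with no filter on low counts (-1.59, 0.0516). Of 19 caput markers outside the initial segment, 7 rose and 3 fell (10 and 3 adjusted over the list alone). The retinoid-binding lipocalin gene Lcn5 rose 5.42-fold from 45.97 ± 7.12 CPM and the sperm-binding protein gene Bsph1 2.64-fold, whereas Defb21 fell 4.22-fold and Ly6g5b 1.58-fold. Of 11 corpus and cauda markers, 3 rose and 2 fell (4 and 2 adjusted over the list alone), among them Gstm2, which rose 1.30-fold, and Defb48, which fell 1.59-fold. None of these lists passed camera with all libraries (Benjamini-Hochberg adjusted p = 0.183, 0.147 and 0.599). The initial segment list passed without control 337 (0.0114), also with knockout 336 left out too (0.0481), and the caput list without control 335 (0.00059).

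Secreted host-defence and carrier proteins followed no single direction. Of 24 beta-defensin genes, 7 rose and 5 fell (11 and 5 adjusted over the list alone), with Defb19 falling by 2.31 (SE 0.28). Of 7 lipocalin genes, 4 rose and 2 fell by both adjustments, with Lcn5 at 2.44 (SE 0.26) and Lcn9 falling by 0.50 (SE 0.10) from 10370 ± 515 CPM (SD, n = 3). Of 27 cystatin and WFDC protease inhibitor genes, 2 rose and 3 fell by both adjustments, with Wfdc6a rising by 0.73 (SE 0.06) and Cst3 falling by 0.50 (SE 0.08). The median log2 fold change of these 27 genes was 0.30, with 22 of them not called. Members of these families resemble one another closely, so single defensin values are uncertain. None of the 3 lists passed camera with all libraries (Benjamini-Hochberg adjusted p = 0.374, 0.240 and 0.570). The beta-defensins and the lipocalins passed without control 335 (0.00452 and 0.00312).

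Genes of lipid synthesis and of stress responses were tested as lists. Of 21 fatty acid synthesis genes, 9 rose and 0 fell, and 12 rose when adjusted over the list alone. The desaturase genes Fads2 and Fads1 rose by 0.66 (SE 0.09) and 0.42 (SE 0.07), the triglyceride synthesis gene Dgat2 by 0.66 (SE 0.10) and the malic enzyme gene Me1 by 0.75 (SE 0.13). Of 21 genes of the ER stress and amino acid response, 8 rose and 1 fell by both adjustments. The asparagine synthetase gene Asns rose by 1.07 (SE 0.10), the transcription factor gene Atf3 by 2.24 (SE 0.35) and the ER chaperone gene Calr by 0.44 (SE 0.08). Camera with a preset correlation passed both lists (Benjamini-Hochberg adjusted p = 0.00365 and 0.0146), with adjusted p = 0.580 and 0.647 with an estimated correlation. The ER stress list did not pass without control 337 (0.0612) or without control 337 and knockout 336 together (0.0825), an alternative chosen after seeing the data, or with fry (0.0557). Of 22 cholesterol synthesis genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone), with Fdps rising by 0.46 (SE 0.10) and Idi1 falling by 0.51 (SE 0.09). Without control 337 and knockout 336 Fdps was at 0.38 (edgeR adjusted p = 0.0643). Of 16 glycolysis genes, 4 rose and 0 fell by both adjustments, among them Tpi1 at 0.44 (SE 0.08). These lists did not pass (adjusted p = 0.651 and 0.0976). The glycolysis list passed camera with limma-voom (0.0139, and 0.00793 with sample weights) and with no filter on low counts (0.0211).

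**Figure D3:**
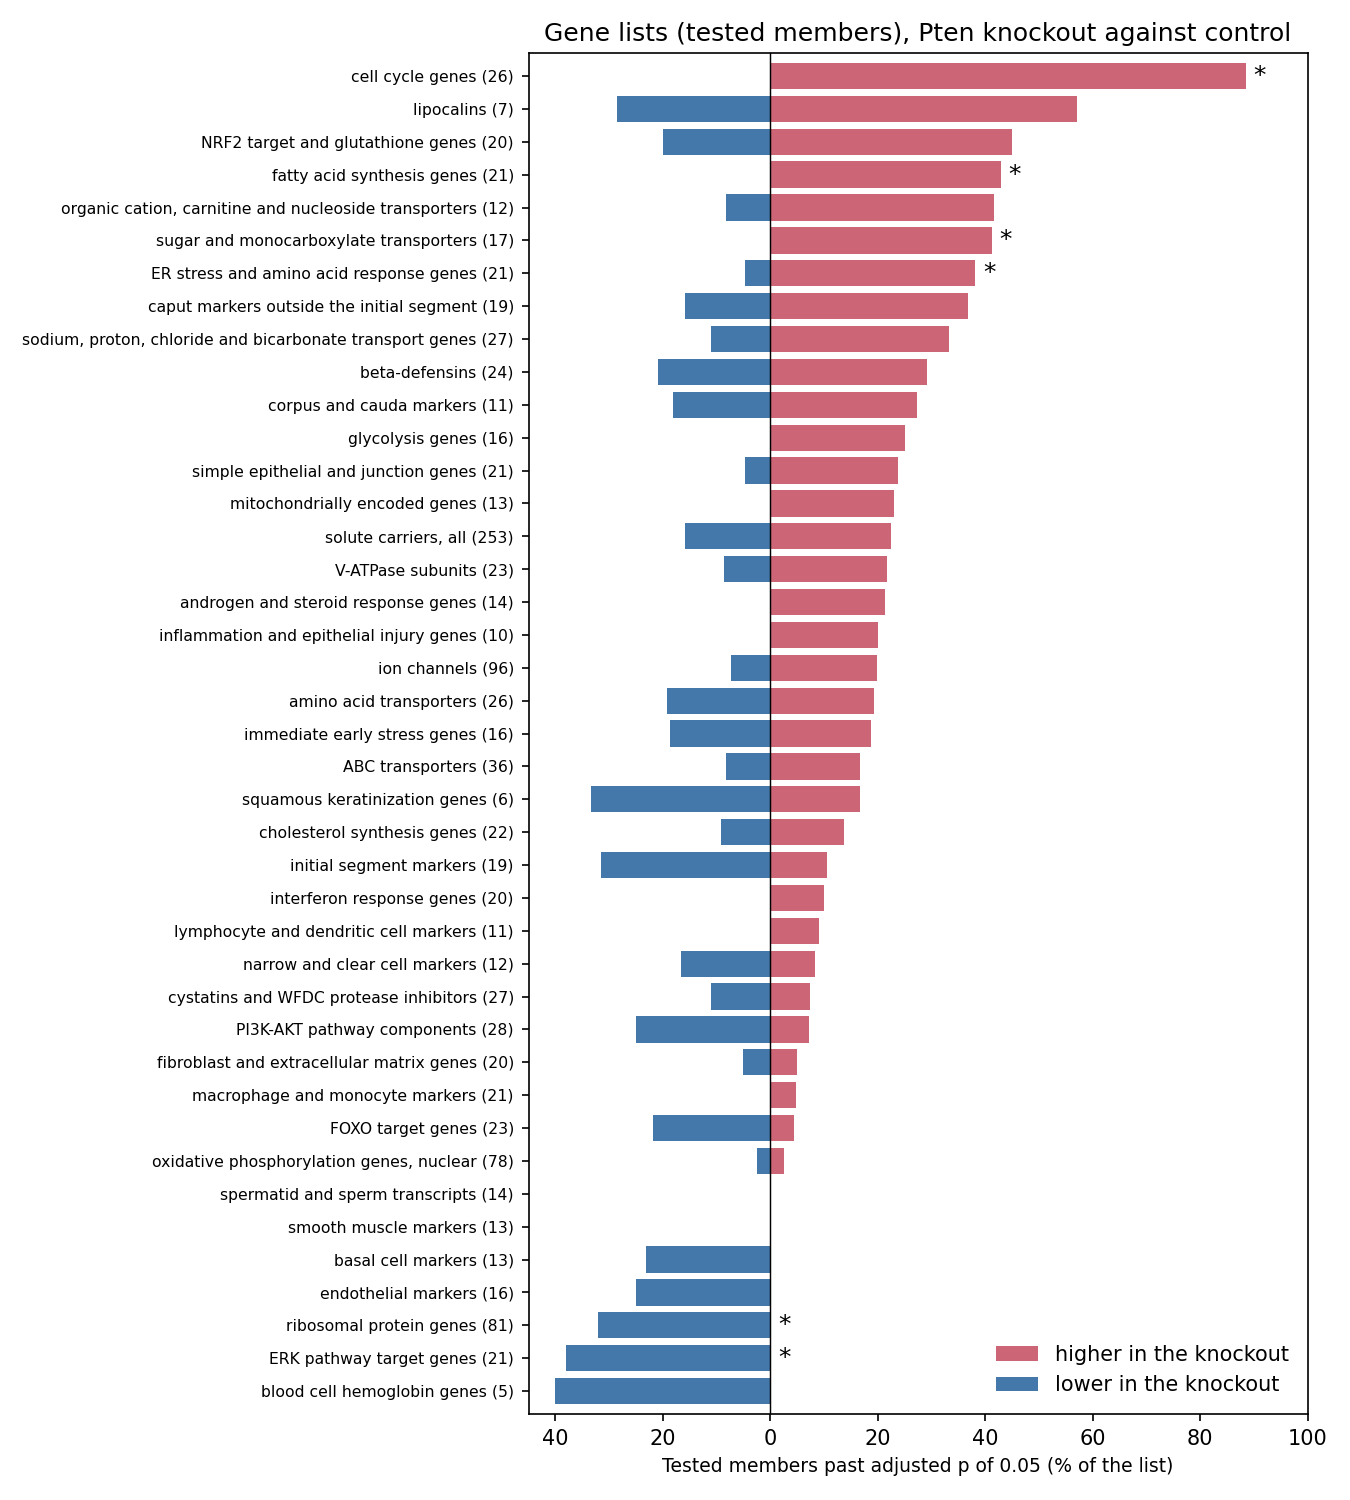
Percent of the tested members of 41 gene lists that passed an adjusted p of 0.05, with genes higher in the knockout drawn to the right of 0 and genes lower to the left, and the number tested in brackets. A star marks the 6 lists that passed the camera test with a preset correlation, led by the cell cycle genes with 23 of 26 higher.

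Of 20 NRF2 target and glutathione genes, 9 rose and 4 fell (10 and 5 adjusted over the list alone). The glutathione transferase genes Gsta4 and Gsta3 rose 2.02-fold and 2.04-fold, while Slc7a11 was 2.88-fold lower. Of 14 androgen and steroid response genes, 3 rose and 0 fell by both adjustments. Srd5a2, the enzyme that makes dihydrotestosterone, rose 2.32-fold from 122 ± 8.17 to 283 ± 9.07 CPM (SD, n = 3), and the steroid-induced gene Fkbp5 rose 1.73-fold. Of 16 immediate early stress genes, 3 rose and 3 fell (4 and 5 adjusted over the list alone), with the heat shock genes Hspa1b and Hspa1a rising 2.04-fold and 2.21-fold and Ier2 falling 1.31-fold. Of 20 interferon response genes, 2 rose and 0 fell (1 and 0 adjusted over the list alone), with Isg15 1.65-fold higher. Of 10 tested inflammation and epithelial injury genes, 2 rose and 0 fell by both adjustments. They were the secreted chaperone gene Clu, at 2676 ± 1746 CPM against 453 ± 36.9 CPM (SD, n = 3), and Lcn2, 1.29-fold higher. The edgeR call of Clu was lost without each single library except knockout 333, with adjusted p between 0.0746 and 0.144, and its log2 fold change of 2.56 was 1.96 without knockout 336. It was also lost with limma-voom (0.0501), with no filter on low counts (0.0775), with a term for the sample number range (0.0833) and without control 337 and knockout 336 together (1.95, 0.211). The call of Lcn2 was lost without control 335 (0.37, 0.0579) or 344 (0.36, 0.0587). Of 78 nuclear genes of oxidative phosphorylation, 2 rose and 2 fell (1 and 0 adjusted over the list alone), with Ndufv3 1.26-fold higher. Of 13 mitochondrially encoded genes, 3 rose and 0 fell by both adjustments, with mt-Nd6 1.30-fold higher, a gene that overlaps its neighbour on the opposite strand. Camera with Benjamini-Hochberg adjustment passed none of these 7 lists with all libraries (adjusted p = 0.175, 0.147, 0.872, 0.379, 0.787, 0.926 and 0.299 in this order), and the NRF2 list passed without knockout 333 (0.0145).

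Markers of other cells of the epididymis were measured beside these groups. Of 13 basal cell markers, 3 fell and 0 rose (3 and 1 adjusted over the list alone), with the basal cell factor gene Trp63 falling 1.82-fold and Dst 1.68-fold. Of 12 narrow and clear cell markers, 1 rose and 2 fell by both adjustments, with the proton pump subunit gene Atp6v0d2 falling 1.66-fold and the carbonic anhydrase gene Car12 rising 4.42-fold. The median log2 fold change of these 12 markers was 1.30, with 9 of them not called. Of 21 simple epithelial and junction genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with the cadherin gene Cdh1 rising 1.33-fold, Tjp3 1.95-fold and Cgn 1.61-fold. Of 6 tested squamous keratinization genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone), among them Krt23, which fell 10.3-fold, and Krt10, which rose 2.31-fold. Camera with Benjamini-Hochberg adjustment passed none of these with all libraries (adjusted p = 0.172, 0.599, 0.0976 and 0.0872). The junction list passed without knockout 333 (0.0129), and the keratinization list without knockout 336 (0.00717) or 345 (0.0328). The junction list also passed with limma-voom (0.0429, and 0.0179 with sample weights), with no filter on low counts (0.0196) and with GC and length trends removed (0.0488). The keratinization list also passed with DESeq2 (0.00695) and without control 337 and knockout 336 together (0.00292).

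Immune and stromal markers were tested in the same way. Of 21 macrophage and monocyte markers, 1 rose and 0 fell by both adjustments, which was Cd68 at 1.94-fold, and their summed CPM was 727 in knockouts and 714 in controls. The Cd68 call was lost without control 337 and knockout 336 together, an alternative chosen after seeing the data, with an edgeR adjusted p of 0.0513. Of 11 tested lymphocyte and dendritic cell markers, 1 rose and 0 fell by both adjustments, which was Cd2 at 2.45-fold. None of 3 tested neutrophil and mast cell markers passed by either adjustment, with Kit at a log2 fold change of 0.34 (SE 0.17). The member Mmp9, at -0.71, passed without knockout 333 (-1.24, edgeR adjusted p = 0.0401). Of 20 fibroblast and matrix genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone), with Pdgfra falling 1.45-fold. None of 13 smooth muscle markers passed by either adjustment, with Mylk at -0.22 (SE 0.10), which passed without knockout 333 (-0.32, edgeR adjusted p = 0.0276). Of 16 endothelial markers, 4 fell and 0 rose by both adjustments, with Eng at -0.87 (SE 0.19), whose call was lost without knockout 345 (-0.81, edgeR adjusted p = 0.0615) and with no filter on low counts (-0.86, 0.0556). Of 5 hemoglobin and red cell genes, 2 fell and 0 rose (3 and 0 adjusted over the list alone), with Hbb-bs falling 1.80-fold. Of 4 tested adipocyte markers, 1 rose, also when adjusted over the list alone, which was Plin4 at 1.44 (SE 0.40), and its call was lost without control 337 (1.24, 0.127), control 344 (1.33, 0.141), knockout 336 (1.60, 0.0704) or knockout 345 (0.96, 0.0674). Plin4 was also lost with limma-voom (0.0576), with no filter on low counts (0.116), with a term for the sample number range (0.0504) and without control 337 and knockout 336 together (0.170). None of 14 spermatid and sperm transcripts passed by either adjustment, with Odf2 at -0.14 (SE 0.09). Camera with Benjamini-Hochberg adjustment passed none of the lists with 5 or more tested members (adjusted p = 0.790 for macrophages, 0.930 for lymphocytes, 0.256 for fibroblasts, 0.876 for smooth muscle, 0.1399 for endothelium, 0.144 for red cells and 0.803 for sperm). Without control 335 the fibroblast and endothelial lists passed (0.0354 and 0.00822), as they did without knockout 333 (0.0432 and 0.00521), and without control 337 the red cell list did (0.00774, and 0.00829 with knockout 336 left out too).

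Across the 41 lists tested, 6 passed camera with a preset correlation of 0.01, 4 upward and 2 downward, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.580. With fry, which asks only whether the genes of a list move on balance in 1 direction and does not compare them with other genes, 16 lists passed, and 36 passed its test for change in either direction. The median and the mean log2 fold change of a list had opposite signs for the initial segment markers (-0.29 and 0.19, camera direction down), the squamous keratinization genes (0.24 and -0.25, down), the transporters of organic cations, carnitine and nucleosides (0.14 and -0.04, up) and the immediate early genes (-0.08 and 0.08, up). The same held for the nuclear oxidative phosphorylation genes (-0.0047 and 0.0088, down) and the adipocyte markers (-0.17 and 0.20, untested). The lymphocyte list had a median of -0.17 and a mean of -0.21 while camera gave it an upward direction.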

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

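Of 183 single genes followed past the threshold, 141 passed under each alternative that tested them, at most 16, and no gene or list past the threshold turned its direction and passed. Counts of called genes, 3238 with all libraries, lay between 2699 and 3870 under other normalizations, tests, filters and terms, and DESeq2 called 3075, of which 2824 were shared. By construction an adjusted p under 0.01 left 1665 (988 higher, 677 lower) and a log2 fold change of at least 1 left 898 (614 higher, 284 lower). Leaving out 1 library gave 1955 to 3324 calls, 1152 to 1960 higher and 803 to 1364 lower. The lowest of each came without control 344, and 909 were lower without control 335, where fewer samples were tested. Lists past the threshold ranged from 6 to 11, with 11 without control 335 or knockout 333, and were 0 with camera at an estimated correlation and 16 with fry; the cause was not tested. Pten lay between -0.823 (without control 337) and -0.5592 (without control 335). It missed the threshold without controls 335 or 344 (-0.5934) or knockouts 336 (-0.6207) or 345 (-0.6323), and with no filter on low counts (-0.6522), where 23116 genes were tested. The fits chosen after seeing the data called 2658 genes without control 337 and knockout 336 (Pten -0.7798) and 3364 with GC and length trends removed (Pten -0.7021). Genes under 0.212 CPM hold fewer than 3 counts in the smallest library, which limits calls among scarce genes.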

Other observations

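The gene families, the lysosomal list, the T-cell receptor signalling genes, the other single genes added here and all tests of explanations except those of the splits of libraries and of matched abundance were chosen after results were seen. Of 39 lysosomal genes, 22 rose and 1 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The sialidase gene Neu1 rose by 0.89 (SE 0.10), the progranulin gene Grn by 0.66 (SE 0.08), the protease gene Ctsb by 0.65 (SE 0.10) and Lamp1 by 0.53 (SE 0.08), whereas the sulfatase gene Sgsh fell by 0.81 (SE 0.14), all on the log2 scale. Camera gave an adjusted p = 8.25e-09 with a preset correlation and an adjusted p = 0.172 with an estimated correlation, and a list chosen on these samples is no independent evidence of its direction. Of 15 tested genes known from T-cell receptor signalling, picked because Zap70 had fallen, 2 rose and 4 fell, with a median log2 fold change of -0.07. Besides Zap70, Lat fell by 1.98 (SE 0.22), Syk by 1.51 (SE 0.24) and Was by 1.44 (SE 0.13). Plcg2 rose by 1.22 (SE 0.19) and Ptpn22 by 0.66 (SE 0.07). Camera gave this list an adjusted p = 0.0467 with a preset correlation and 0.172 with an estimated correlation. The adjustment ran over this list and the lysosomal list alone. Zap70, whose fall prompted the list, is itself a tested member. The result with a preset correlation is therefore no independent evidence that T-cell receptor signalling genes fell as a set. The Syk call was lost without control 337 and knockout 336 together (-1.35, adjusted p = 0.0607). The T-cell gene Cd3e was at 1.16 CPM in controls and 1.10 CPM in knockouts.

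A screen of 218 gene families with 8 or more tested members gave 9 past camera with a preset correlation, 4 upward and 5 downward, and 0 with an estimated correlation (adjusted p = 0.994 for each with an estimated correlation). Of 11 aldo-keto reductase genes, 6 rose and 1 fell, with Akr1c19 at 1.92 (SE 0.13). Of 8 Spink protease inhibitor genes, 2 rose, Spink5 at 2.68 (SE 0.34) and Spink10 at 1.67 (SE 0.16), and the Spink5 call was lost without control 337 and knockout 336 together (2.36, adjusted p = 0.101). Of 17 semaphorin genes, 4 rose and 6 fell, and Sema7a fell 8.53-fold from 135 to 15.8 CPM. Hoxb7 fell by 0.90 (SE 0.08) and Hoxb1 by 2.24 (SE 0.21), in a family with 3 of 9 lower. Among transporters, 4 of 8 Slco genes were called higher and 1 lower, and 4 of 9 Abca genes higher and 0 lower. Both families passed upward (camera adjusted p = 0.0179 for each with a preset correlation). The remaining families past this test were Rpl, Rps and Bmp, all downward.

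The 6 libraries can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. The real split called 3238 genes and was 1 of 10 to call as many, and the highest count of another split was 0. Each other split mixed knockouts and controls in both groups, so the difference between them widened the spread within its groups. The count of 0 is therefore no measure of how many genes chance would call. The age of the samples and the genotype of the controls are not given, and an effect of the genotype could not be separated from these.

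Some initial segment markers fell and some caput markers rose, which might come from knockout pieces that held more downstream tissue. If such tissue made up no more than 50% of the pieces, no marker would fall by over 1 log2 unit through it. Among the 6 initial segment markers that fell only 1, Rnase10, fell that far by 2 SE or more, so the test cannot tell. Rnase10 is also the gene whose promoter drives Cre here, and whether the Cre line alters its level was not tested. Its fall can therefore not be read as a share of tissue. If the knockout pieces came almost wholly from downstream tissue, Rnase10 would be nearly absent, and 32.88% of its control level remained. For the same reason, and with no profile of the segments, this cannot tell either. A change of the epithelium by loss of Pten was not tested apart from these.

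The cell cycle list, with 23 of 26 higher, had a median log2 fold change of 1.28, and a rise shared by scarce genes, or cycling immune cells, might account for it. Of 10000 lists matched on abundance, 0% reached that median, the highest being 0.475, so low abundance does not account for it. Those lists were drawn gene by gene, so the 0% is no chance level for genes that move together. Camera with an estimated correlation gave the cell cycle list an adjusted p = 0.580. The lymphocyte list had a median of -0.1703 (SE 0.254), and its summed CPM was 28.5 in controls and 23.2 in knockouts. Of its 11 tested members 10 were not called, and the other, Cd2, rose by 1.29 (SE 0.17). The markers had a median of 1.16 CPM in controls, which is too low to decide, so cycling lymphocytes stay open. The macrophage list differed by 13.25 CPM (SE 53.7), and a small added share of cycling macrophages could not be seen against that spread. Division of the epithelial cells themselves was not tested.

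The ribosomal protein list, with 26 of 81 lower, had a median log2 fold change of -0.20, which might come from GC content or transcript length, or from a lower share of stromal cells. With smooth trends over GC content and length removed the median was -0.1922 and the list still passed (camera adjusted p = 2.14e-05), so these trends as the whole cause do not account for it. Before that removal the list had an adjusted p = 0.714 with an estimated correlation and 0.0574 with fry. The mean log2 CPM of fibroblast, smooth muscle and endothelial lists differed by -0.1682 (SE 0.201), which cannot tell whether a lower share of these cells took part. An effect of the genotype on ribosomal protein genes was not tested apart from these.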
